A study of Homo sapiens with 21 samples.

How the data were processed

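Total RNA from 2 kinds of primary human cell was profiled on Illumina BeadChips: fibroblast-like synoviocytes (FLS) from patients with rheumatoid arthritis, and human umbilical vein endothelial cells (HUVEC). Each kind of cell was measured without transfection, after transfection with a control siRNA, and after transfection with an siRNA against NFAT5. The FLS table held 9 arrays, 3 per group, and the HUVEC table held 12, 4 per group. The endothelial cells were grown with 20% serum, per the labels. One array's cell type field names synoviocytes while its title and source name endothelial cells; it was grouped by its title.

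For each kind of cell a non-normalized table and a normalized table were used. The non-normalized table holds linear intensity per probe as deposited, with no detection p-value, no control probes and no slide. The deposited normalized table holds log2 values, and on every array its probes had the same rank order as the intensities (lowest Spearman rho 1). It differed from a quantile normalization of log2 intensity by at most 0.0421 in FLS and 0.0372 in HUVEC, so its scale and method were read from the values and no centring was seen. R 2.9.1 is named in the submitters' processing notes; the summarisation and any background correction before deposit are not given in the sources used here. Medians of the normalized columns lay between 7.24 and 7.25 in FLS and at 7.82 on every HUVEC array.

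Intensities were background-corrected with limma's normexp method at an offset of 50, taken to log2 and quantile-normalized within each table. The 2 kinds of cell were run on different chips and normalized apart, so levels are compared only within a table. The design fixed before the data were examined asked for a detection filter, with all probes as the fallback where the tables hold no detection p-value; the fallback was used. Probe names came from the platform annotation. In FLS, 21834 of 24526 probes had 1 gene symbol, 0 had several and 2692 had none. In HUVEC, 28098 of 48803 had 1 symbol, 13 had several and 20692 had none. Entrez identifiers of 21813 and 28059 of the named probes matched the RefSeq gene table, and 0 symbols needed updating. A gene with several probes was represented by the probe with the highest mean, which left 16864 genes in FLS and 18776 in HUVEC; probes of 1 gene that moved in opposite directions are named beside the result. Sex-linked marker genes were removed before any test.

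Genes were tested with limma (version 3.58.1, R 4.3.3; lmFit, then eBayes with an intensity trend) in 1 fit per kind of cell over its 3 groups, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p for a gene comes from limma. A second fit added the replicate number as a block. Deviations from the group means correlated at 0.379 or more between FLS arrays of the same number and at -0.0745 or less between different numbers; in HUVEC these bounds were 0.232 and 0.00112. The numbers therefore pair the arrays, although the labels only call them biological replicates. Blocked values are given where they change the call of a gene or list named in the text within 1 kind of cell. They are also given where they move the total number of changed genes by over 1.5 times. Counts of list members come from the fit without the block unless the block is named.

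Lists of genes fixed before the data were examined (21 lists, 590 entries) were tested with limma's camera at a preset inter-gene correlation of 0.01, with the estimated correlation as an alternative. Genes whose probes both chips carry numbered 16957, above the 16864 tested in FLS. This set therefore differs in part from that of the FLS fit in its genes or the probes used. Its interferon list held 45 members against 44 in the FLS fit. Its osmotic targets of NFAT5 had an FLS median of -0.023 for NFAT5 siRNA against control siRNA, where the FLS fit gave 0.089. An interaction over this set tested the difference between the kinds of cell. Overlap of calls between them, which share no arrays, was tested with a two-sided Fisher's exact test. Levels of NFAT5 were also compared with two-sided exact permutation tests.

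Genes were named by a rule fixed at the same time. It takes NFAT5, the 12 largest rises and 12 largest falls with NFAT5 siRNA among genes past the threshold whose groups do not overlap, up to 4 members of each described list with the smallest p, 5 of each direction for control siRNA, and 5 of each direction for the difference between the kinds of cell. Where under 5 genes passed, the 5 smallest p in that direction are given as not passing. Provisional gene names were skipped.

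The fits were tested on simulated arrays with the real genes' means and spreads. Changes were seeded only in genes above the median mean level, so the shares below hold for brighter genes. The simulated spread was independent between genes and between arrays, without the pairing seen in the data. For NFAT5 siRNA against control siRNA in FLS (16864 genes), 52.0% of seeded changes of 1 on the log2 scale and 92.0% of changes of 2 were called. In HUVEC (18776 genes) these shares were 92.0% and 97.0%. For the difference between the kinds of cell (16957 genes) they were 60.0% and 88.0%. The alternatives tried were no background correction, median scaling, the deposited normalized values, the mean of a gene's probes, only the groups compared, the replicate block, array weights, each array left out in turn, each kind of cell's own spread for the difference, and unadjusted p under 0.01 for the overlap. A filter on dim probes, the replicate block together with an estimated correlation, and the list test of the difference were added after seeing the data.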

Results

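Genome-wide mRNA levels were measured on 21 arrays. FLS, the fibroblasts of the joint lining, were taken from patients with rheumatoid arthritis and gave 9 arrays, with 3 non-transfected cultures, 3 given a control siRNA and 3 given an siRNA against NFAT5. HUVEC, endothelial cells of the umbilical vein, gave 12 arrays, with 4 in each of the same groups. Median raw intensity ran from 126 to 187 on the FLS arrays and from 202 to 259 on the HUVEC arrays. Replicates of a group correlated at 0.975 to 0.986 in FLS and at 0.974 to 0.980 in HUVEC. The HUVEC array with the conflicting cell type field resembled its group. On the non-transfected HUVEC arrays, this one included, mean log2 levels were 9.98 to 10.5 for endothelial markers and 8.18 to 8.53 for fibroblast markers. Within the FLS table the order was the other way, at 6.82 to 7.11 for endothelial and 12.2 to 12.7 for fibroblast markers on the non-transfected arrays. Nothing in the labels says whether replicates came from separate donors, so p-values measure the spread between these cultures, and the number of arrays limits their precision.

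NFAT5, the transcription factor of the hyperosmotic stress response, was lowered by its siRNA in both kinds of cell. In FLS its log2 level was 9.31 ± 0.41 (SD, n = 3) with control siRNA and 7.67 ± 0.37 (SD, n = 3) with NFAT5 siRNA. The log2 change was -1.64 ± 0.25 (SE; adjusted p = 0.0127), which left 32% of the control signal, and the exact permutation p was 0.1, the smallest that 3 against 3 arrays allow. The FLS call ended without control siRNA replicate 1 or 2 or NFAT5 siRNA replicate 3 (highest adjusted p = 0.0609). In HUVEC the level went from 9.27 ± 0.28 (SD, n = 4) to 8.23 ± 0.30 (SD, n = 4), a change of -1.04 ± 0.18 (SE; adjusted p = 0.00186) that left 48.6%, with an exact permutation p of 0.0286, the smallest that 4 against 4 allow. Control siRNA against no transfection gave changes of 0.11 in FLS and -0.03 in HUVEC. These values are for the brightest of the 3 NFAT5 probes. A second probe fell from 8.12 to 6.78 in FLS and from 7.86 to 7.17 in HUVEC. Its HUVEC groups overlapped, with control siRNA replicate 2 at 7.49 and NFAT5 siRNA replicate 1 at 7.59. The third probe lies near the floor of the arrays and moved the other way. With the mean of all 3 probes the HUVEC fall did not pass (adjusted p = 0.0747).

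**Figure D1:**
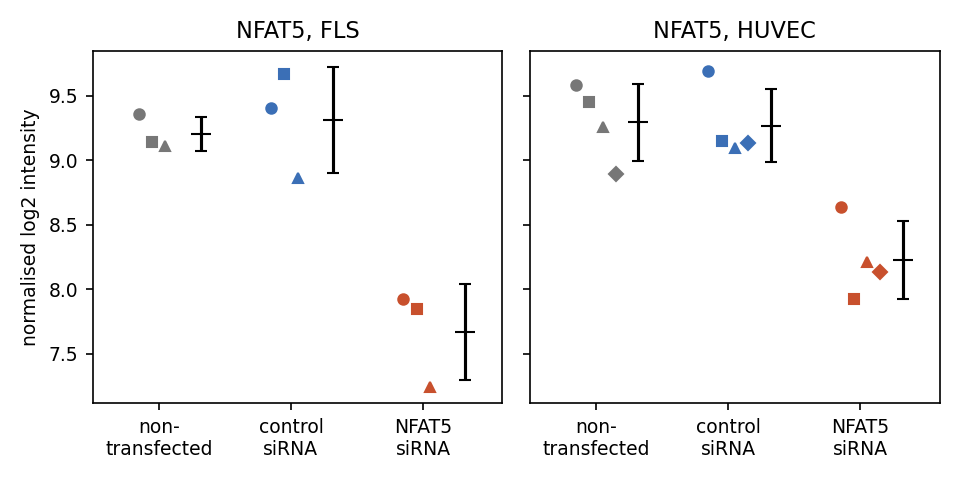
Normalised log2 intensity of the NFAT5 probe used on each array, by group, in FLS and HUVEC; each symbol shape is a replicate number, and the bars give the mean and SD. All NFAT5 siRNA arrays lie below all control siRNA and non-transfected arrays, with means of 7.67 in FLS and 8.23 in HUVEC.

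The first comparison asked what lowering NFAT5 does in rheumatoid synoviocytes. Some genes of cell division fell: of 40 mitosis and G2/M genes 12 fell and 0 rose, and of 37 replication genes 7 fell and 0 rose. With the replicate block 33 mitosis genes fell and 1 rose, and 25 replication genes fell and 0 rose. Both list calls were lost with an estimated correlation (camera adjusted p = 0.333 for each). The largest falls included TNFRSF11B, the decoy receptor osteoprotegerin (log2 change -2.70 ± 0.41, SE), F3, the clotting initiator tissue factor (-2.66 ± 0.46), and RECK, a membrane inhibitor of matrix proteases (-2.48 ± 0.21). The largest rises were GJB2, the gap junction protein connexin 26 (3.27 ± 0.51), and GDF15, a stress-induced cytokine (2.79 ± 0.24). In all, 387 of 16864 genes changed, 171 up and 216 down, and 54 of the rises and 116 of the falls were at least 2-fold.

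After GJB2 and GDF15 the largest rises were RGS17 (1.98), CDK14 (1.94), MERTK (1.85), the mitochondrial superoxide dismutase SOD2 (1.68), the lysosomal cholesterol transporter NPC1 (1.66), the histone gene H2BC5 (1.64), RAB22A (1.63), the aquaporin AQP9 (1.61), C2CD2 (1.59) and ZFYVE26 (1.56). The control siRNA levels of MERTK and AQP9 lay below the median signal of the arrays. RAB22A and CDK14 stood at -0.99 and -1.25 in control siRNA against non-transfected FLS, and against non-transfected cells NFAT5 siRNA left them at 0.64 (adjusted p = 0.103; 0.00968 with the replicate block) and 0.68 (adjusted p = 0.471; 0.0251 with the block). Further large falls were DR1 (-2.53), PRSS35 (-2.38), LEPROTL1 (-2.08), the soluble pattern receptor PTX3 (-2.01), the calcineurin regulator RCAN1 (-1.99), SPIN4 (-1.94), ALPK2 (-1.83), the junction protein JAM2 (-1.83) and RRM2 (-1.76), a subunit of the enzyme that makes deoxyribonucleotides. Adjusted p for these genes lay between 0.000511 for LEPROTL1 and 0.0491 for SOD2.

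The mitosis list fell with a median log2 change of -0.93 (camera adjusted p = 2.717e-25; adjusted p = 0.333 with an estimated correlation). Its members NDC80 (-1.14), CDK1 (-1.22), CENPF (-1.11) and CEP55 (-1.08) fell, and 31 of the 40 fell when adjusted over the list alone. The replication list fell by 0.68 at the median (median -0.68, adjusted p = 1.431e-17; adjusted p = 0.333 with an estimated correlation), with falls of RRM1 (-0.78), PRIM1 (-1.12) and TK1 (-1.14), and 23 of 37 adjusted over the list alone. Interferon-stimulated genes rose as a list (median 0.45, adjusted p = 0.00356; adjusted p = 0.587 with an estimated correlation) with 0 of 44 members past the test by either adjustment. With the replicate block 18 rose and 1 fell, among them PSMB8 (0.72, adjusted p = 0.00104) and IFIT3 (0.99, adjusted p = 0.0144). The list call ended with array weights (adjusted p = 0.103), without control siRNA replicate 1 (mean 0.17, adjusted p = 0.204) and without NFAT5 siRNA replicate 2 (mean 0.21, adjusted p = 0.183). Extracellular matrix genes fell as a list (median -0.26, adjusted p = 0.0144; adjusted p = 0.419 with an estimated correlation) with 0 of 34 members past the test and 2 adjusted over the list alone. With the block 13 fell, among them FBN1 (-0.66, adjusted p = 0.00380), LOXL1 (-0.70, adjusted p = 0.00408), COL12A1 (-1.11, adjusted p = 0.000344, probes of both signs) and THBS1 (-1.80, adjusted p = 1.103e-05). The list call ended without control siRNA replicate 1 (mean -0.22, adjusted p = 0.0612) and without NFAT5 siRNA replicate 3 (mean -0.17, adjusted p = 0.231).

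Cholesterol and fatty acid synthesis genes fell as a list (median -0.14, adjusted p = 0.00648; adjusted p = 0.563 with an estimated correlation), with falls of the elongase ELOVL6 (-1.49) and of LSS (-1.06), whose probes disagreed in direction. They were 2 of 25 members, and 2 adjusted over the list alone. The list call ended without control siRNA replicate 1 (adjusted p = 0.0612) and without NFAT5 siRNA replicate 1, where the mean went from -0.29 to -0.12 (adjusted p = 0.243); without NFAT5 siRNA replicate 2 the mean was -0.45. The TGF-beta and contractile list fell (median -0.17, adjusted p = 0.0219; adjusted p = 0.340 with an estimated correlation) with 1 of 24 members past the test, CCN2 (-1.29), and 3 adjusted over the list alone; the list call ended without control siRNA replicate 1 (adjusted p = 0.0612), without NFAT5 siRNA replicate 3 (0.180) and with bright probes only (0.117). Inflammatory cytokines and chemokines did not pass as a list (median 0.13, adjusted p = 0.0538), although CXCL1 (1.53) and CCL26 (0.81) rose. The monocyte attractant CCL2 stood at -1.81 (adjusted p = 0.0614; 0.000929 with the replicate block) and the neutrophil attractant CXCL6 at 2.68 (adjusted p = 0.119; 0.00819 with the block). Known osmotic targets of NFAT5 showed 0 calls among 17 members, 1 fall adjusted over the list alone and a median of 0.09 (adjusted p = 0.836). With the block 3 members rose and 2 fell, among them SLC38A2 (-0.89, adjusted p = 0.000493) and the taurine transporter SLC6A6 (0.90, adjusted p = 0.00468).

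Single members also changed in lists that did not pass. Beside CXCL1, CCL26, GDF15 and JAM2 these were the protease CTSL (0.59), the apoptosome protein APAF1 (-0.94), the glycolytic enzyme PFKP (-1.37) and HPRT1 among the housekeeping genes (-0.90). Matrix proteases (median 0.17, adjusted p = 0.0655), p53 targets (0.14, 0.0863), apoptosis regulators (0.16, 0.146), heat shock genes (0.16, 0.121), hypoxia genes (-0.12, 0.146), angiogenic factors (-0.08, 0.219), adhesion molecules (0.06, 0.809) and the unfolded protein response (-0.05, 0.544) gave no call. Marker lists of endothelial (0.03, 0.680), fibroblast (-0.23, 0.219), leukocyte (0.02, 0.543) and smooth muscle cells (-0.07, 0.348), and housekeeping genes (-0.03, 0.543), gave none either. With the replicate block 2537 genes changed, 1194 up and 1343 down, and all 387 remained among them; the inflammatory list (adjusted p = 0.0420; adjusted p = 0.317 with an estimated correlation) and the fibroblast list (adjusted p = 0.00648; adjusted p = 0.250 with an estimated correlation) then passed too. With 1 array left out in turn the count lay between 53 and 300, and with the mean of their probes MERTK, SOD2, CXCL1, APAF1 and LSS did not pass. With median scaling MERTK, CXCL1, CTSL, RRM1, TK1, PFKP, CCN2 and HPRT1 did not pass, and with only the 2 groups compared MERTK, SOD2, AQP9, CCL26, CXCL1, CTSL, TK1, APAF1, LSS and HPRT1 did not. GDF15, RGS17, H2BC5, RAB22A, C2CD2, ZFYVE26, RECK, DR1, LEPROTL1, RCAN1, SPIN4 and ALPK2 passed with each array left out in turn; each of the other largest rises and falls lost its call in at least 1 case, as did CDK1, CENPF, CEP55, RRM1, PRIM1, TK1, ELOVL6, LSS, CCN2, CXCL1, CCL26, CTSL, APAF1, PFKP and HPRT1.

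Transfection with the control siRNA changed 0 genes in FLS by limma (376 at an unadjusted p under 0.05). These 376 are a smaller share of the 16864 genes than the 0.05 expected with no change. Between these groups, deviations of same-number arrays correlated at 0.824 to 0.866, which this fit does not take out. The 0 calls therefore do not show that little changed. With the replicate block 16 genes changed, all of them falls. Of the genes with the smallest p, WSB2 (0.75), TRIM55 (0.39), OR6K2 (0.29), GDF5 (0.78) and HORMAD2 (0.39) were higher and did not pass in either fit; TRIM55, OR6K2 and HORMAD2 lay below the median signal. PHACTR2 (-0.87), ZDHHC16 (-1.15), ADAM15 (-0.68), G3BP2 (-0.78, probes of both signs) and RAB22A (-0.99) were lower, with adjusted p = 0.623, and passed with the block (adjusted p at most 0.0331). As lists, mitosis (median -0.29, adjusted p = 4.896e-13; adjusted p = 0.760 with an estimated correlation) and replication genes (median -0.27, adjusted p = 6.657e-10; adjusted p = 0.760 with an estimated correlation) fell. Targets of p53 rose (median 0.13, adjusted p = 1.941e-05; adjusted p = 0.0415 with an estimated correlation), as did interferon-stimulated genes (median 0.21, adjusted p = 0.00470; adjusted p = 0.865 with an estimated correlation). The interferon call rests on single arrays: the list mean of 0.20 went to -0.074 (adjusted p = 0.262) without control siRNA replicate 2 and to 0.044 (adjusted p = 0.563) without non-transfected replicate 1. The means of the mitosis (-0.30) and replication lists (-0.25) went to -0.17 and -0.14 without control siRNA replicate 3, and the replication mean to -0.12 without non-transfected replicate 1, with both calls kept. No member of these 4 lists passed over all genes or adjusted over the list alone; NUSAP1 stood at -0.45, BIRC5 at -0.77, MCM3 at -0.46, CDKN1A at 0.30 and GADD45A at 0.31. The p53 list did not pass with both the block and an estimated correlation (adjusted p = 0.114).

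Against non-transfected FLS, NFAT5 siRNA changed 354 genes, 108 up and 246 down (2526 with the replicate block). GJB2 and GDF15 (2.91 ± 0.24, SE) rose. TNFRSF11B (-2.24), RECK (-2.23) and DR1 (-2.30) fell here too, while F3 (-2.09, adjusted p = 0.0526; 0.000190 with the block) did not pass.

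The same comparison was made in endothelial cells, where 1573 of 18776 genes changed with NFAT5 siRNA, 788 up and 785 down, and 129 of the rises and 123 of the falls were at least 2-fold. Cell division genes fell: 32 of 41 mitosis genes and 19 of 37 replication genes. Interferon-stimulated genes rose in 29 of 45 cases, led by OAS2 (log2 change 3.05 ± 0.36, SE), and endothelial identity genes rose in 8 of 17. HMOX1, which degrades heme (2.87 ± 0.21), and the matricellular protein CCN3 (2.92 ± 0.21) were among the largest rises. NPPB, the precursor of brain natriuretic peptide (-3.32 ± 0.27), and CCL2 (-2.42 ± 0.37) were among the largest falls.

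Other large rises were IFI44L (2.51), TNFAIP8L3 (2.48), the decoy receptor IL13RA2 (2.39), IFI6 (2.38), OAS1 (2.37), the phosphatase DUSP5 (2.36), the protease ADAMTS9 (2.33), IFIT1 (2.31) and DDIT4L (2.27). Other large falls were GDF7 (-2.71), CBLN2 (-2.70), SHISA3 (-2.42), the gap junction protein GJA4 (-2.38), the prostacyclin synthase PTGIS (-2.29), the arginine transporter SLC7A2 (-2.21), NEK7 (-2.05), ZNF365 (-2.03), RNF150 (-2.01) and the actin ACTC1 (-2.01). Adjusted p lay between 6.455e-07 for DUSP5 and 0.0310 for GJA4. The lower group of IL13RA2, GJA4 and ACTC1 lay below the median signal of the arrays. IFI6, IFIT1, GDF7, SLC7A2, ZNF365 and ACTC1 each had at least 1 other probe of the opposite sign, and with the mean of its probes IFI6 did not pass (adjusted p = 0.785), nor did ACTC1 (0.0784).

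The mitosis list fell (median -0.73, camera adjusted p = 4.177e-32; adjusted p = 0.0834 with an estimated correlation). CCNB2 (-1.01), HMMR (-1.08), RACGAP1 (-0.98) and UBE2C (-1.22) led it, and 37 of 41 fell and 1 rose when adjusted over the list alone. The replication list fell (median -0.46, adjusted p = 2.875e-17; adjusted p = 0.0834 with an estimated correlation) with falls of RRM2 (-1.14), POLA2 (-0.70), RRM1 (-0.58) and CHAF1B (-0.86). There 1 member rose, and 24 fell and 1 rose adjusted over the list alone. Interferon-stimulated genes rose as a list (median 0.78, adjusted p = 7.248e-24; adjusted p = 0.0834 with an estimated correlation). IFI27 (1.08), SAMD9 (1.27), IRF7 (1.61, probes of both signs) and PARP9 (1.60) had the smallest p, 1 member fell, and 33 rose and 1 fell adjusted over the list alone. These genes were far lower in control siRNA than in non-transfected HUVEC: against non-transfected cells NFAT5 siRNA left OAS2 at -1.57 ± 0.36 (SE), and 39 of the 45 members fell with a median of -1.41.

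Endothelial markers rose as a list (median 0.63, adjusted p = 6.585e-05; adjusted p = 0.146 with an estimated correlation). PECAM1 (0.99), CDH5 (0.63), the VEGF receptor KDR (0.91) and ESAM (1.17) rose, and 9 rose and 1 fell adjusted over the list alone. Adhesion molecules rose (median 0.31, adjusted p = 0.00301; adjusted p = 0.146 with an estimated correlation) in 8 of 20 members including MCAM (0.88), while ALCAM fell (-0.78); 9 rose and 1 fell adjusted over the list alone. Fibroblast markers gave no list call (median -0.06, adjusted p = 0.333), with falls of COL3A1 (-0.78) and COL1A2 (-0.83), and CDH11 stood at -0.35 (adjusted p = 0.0508; 0.00137 with the replicate block). Smooth muscle markers gave none (0.18, adjusted p = 0.124), with rises of MCAM and ACTA2 (1.62) and a fall of TAGLN (-0.87). Leukocyte markers gave none (-0.13, adjusted p = 0.762), with a rise of CD68 (0.58).

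Angiogenic factors rose as a list (median 0.16, adjusted p = 0.0168; adjusted p = 0.146 with an estimated correlation) with members on both sides. PGF (1.28) and JAG1 (1.08) were among 9 rises and EFNB2 (-1.19) and FGF2 (-1.30) among 5 falls of 36, and 15 rose and 5 fell adjusted over the list alone. Matrix proteases rose (median 0.13, adjusted p = 0.00301; adjusted p = 0.0834 with an estimated correlation) in 5 members including the collagenase MMP1 (2.12), CTSL (0.81), PLAU (0.78) and the inhibitor TIMP2 (0.46), while 1 of 28 fell; 6 rose and 1 fell adjusted over the list alone. Targets of p53 rose (median 0.29, adjusted p = 0.000556; adjusted p = 0.146 with an estimated correlation) in 8 of 25 members, among them AEN (0.60), the death receptor TNFRSF10B (0.48), XPC (0.46) and ZMAT3 (0.36, probes of both signs), with 11 rises and 1 fall adjusted over the list alone. Extracellular matrix genes fell as a list (median -0.24, adjusted p = 0.00309; adjusted p = 0.110 with an estimated correlation), with 6 falls including COL8A1 (-0.66) and THBS1 (-0.48) and a rise of LAMC1 (0.47) among 34, and the same counts adjusted over the list alone.

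Cholesterol and fatty acid genes fell (median -0.18, adjusted p = 0.000463; adjusted p = 0.0834 with an estimated correlation). The 5 falls of 27 members, by either adjustment, included LSS (-1.27, probes of both signs), ACAT2 (-0.66), ELOVL6 (-0.83) and the fatty acid synthase FASN (-0.42). The TGF-beta and contractile list fell (median -0.18, adjusted p = 0.00170; adjusted p = 0.112 with an estimated correlation), with 7 falls and 2 rises of 24. TGFB2 (-1.97), CCN1 (-0.68), the inhibitor SMAD7 (-0.87) and TPM1 (-0.81) fell, and 9 fell and 3 rose adjusted over the list alone. Osmotic targets of NFAT5 gave no list call (median 0.03, adjusted p = 0.439). S100A4 (-0.91) and SLC38A2 (-0.65) fell, while SLC7A5 (0.86) and HSPA1B (0.78) were among 3 rises of 17; adjusted over the list alone, 4 rose and 2 fell.

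Among lists with no call, inflammatory genes (median 0.13, adjusted p = 0.327) held rises of CXCL1 (2.08) and CXCL2 (1.69) beside falls of CCL2 and TNFAIP6 (-1.01); the lower group of CXCL2 and of TNFAIP6 lay below the median signal, so these sizes are rough. Hypoxia genes (0.04, adjusted p = 0.663) held rises of NDRG1 (1.55), the glucose transporter SLC2A3 (2.07) and ANKRD37 (0.70) and a fall of PFKFB4 (-0.69). Heat shock genes (0.08, adjusted p = 0.272) held rises of HSPA1A (0.97) and HSPA1B and falls of HSPA2 (-0.85) and the small chaperone CRYAB (-1.82). The unfolded protein response list (0.05, adjusted p = 0.585) held rises of PPP1R15A (0.87) and TRIB3 (1.04) and falls of MTHFD2 (-0.57) and XBP1 (-0.42). Apoptosis regulators (0.09, adjusted p = 0.929) held falls of APAF1 (-1.09) and BNIP3L (-1.03) and a rise of TNFRSF10A (0.95). Among housekeeping genes (0.03, adjusted p = 0.424) B2M (0.62) and SDHA (0.44) rose. With the replicate block 3115 genes changed, 1575 up and 1540 down, with 1571 called in both fits, and 6 of the 11 called lists also passed with the block and an estimated correlation (mitosis, replication, matrix proteases, extracellular matrix, TGF-beta and endothelial markers). With median scaling of the arrays 781 genes rose and 294 fell, so 72.7% of calls were rises against 50.1% here. With the mean of their probes LSS, ELOVL6, TIMP2, TNFRSF10B, ZMAT3, CD68 and SDHA did not pass. With median scaling SLC38A2, COL3A1, COL1A2, RRM1, XPC, MTHFD2, XBP1, ACAT2, ELOVL6, FASN and PFKFB4 did not, and GJA4 did not without background correction (adjusted p = 0.0585). With 1 array left out in turn ACTC1, GJA4, CXCL1, PLAU, FASN, ELOVL6, ZMAT3, XPC, CD68, COL1A2, COL3A1, HSPA1A, MTHFD2, XBP1 and SDHA lost the call in at least 1 case, and the angiogenic list lost it without control siRNA replicate 2 (adjusted p = 0.0902) and with bright probes only (0.0542).

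**Figure D2:**
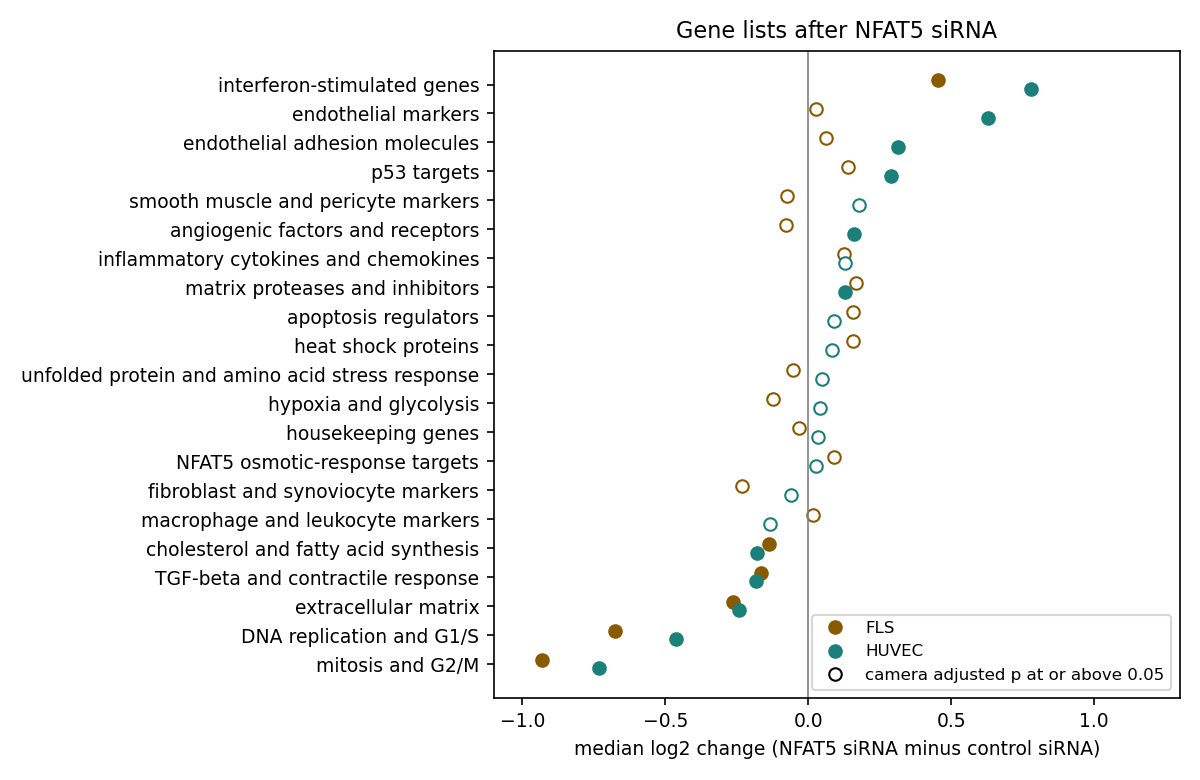
Median log2 change of each gene list, NFAT5 siRNA minus control siRNA, in FLS and HUVEC; filled points have a camera adjusted p under 0.05 at the preset correlation. Mitosis genes lie lowest, at -0.93 in FLS and -0.73 in HUVEC, and interferon-stimulated genes highest, at 0.45 and 0.78.

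In HUVEC interferon-stimulated genes were lower with control siRNA than in non-transfected cells: 40 of 45 fell and 0 rose. The largest falls of all genes were OAS2 (log2 change -4.62 ± 0.36, SE), IFI44L (-4.62 ± 0.36), IFIT1 (-4.55 ± 0.36), IFI6 (-4.26 ± 0.41) and IFITM1 (-4.13 ± 0.39). In all 123 genes changed, 14 up and 109 down. The largest rises were TXNDC12 (1.28), the iron-regulated aconitase ACO1 (1.07), the transcription factor MEF2D (1.02), MTURN (1.01) and the p53 target ZMAT3 (1.00). IFI6 did not pass with the mean of its probes (adjusted p = 0.994).

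The interferon list had a median of -2.20 (camera adjusted p = 4.542e-173) and held with an estimated correlation (adjusted p = 0.000572); MX2 (-3.87), ISG15 (-3.43), HERC6 (-3.26) and PARP9 (-2.89) had the smallest p, and 42 fell adjusted over the list alone. Mitosis (median -0.14, adjusted p = 4.574e-07; adjusted p = 0.411 with an estimated correlation) and replication genes (-0.12, adjusted p = 0.000205; adjusted p = 0.413 with an estimated correlation) fell as lists with no member past the test by either adjustment; CDC20 stood at -0.29, MKI67 at -0.38 and MCM3 at -0.31. Inflammatory genes fell (-0.07, adjusted p = 0.0460; adjusted p = 0.311 with an estimated correlation) with 1 of 29 past the test, the chemokine CCL5 (-1.80), and 4 adjusted over the list alone. Heat shock genes fell (-0.09, adjusted p = 0.0171; adjusted p = 0.244 with an estimated correlation) with no call over all genes and 1 adjusted over the list alone.

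Targets of p53 rose (0.09, adjusted p = 0.00335; adjusted p = 0.311 with an estimated correlation), with ZMAT3 the 1 member called by either adjustment. Extracellular matrix (0.10, adjusted p = 0.0171), cholesterol (0.11, adjusted p = 0.0330) and TGF-beta lists (0.15, adjusted p = 0.0236) rose, each with adjusted p = 0.311 with an estimated correlation; TGFB2 (0.77) was the 1 member called, by either adjustment. In lists without a call, CASP1 (-1.20, probes of both signs), TNFSF10 (-1.37), CTSL (-0.56) and B2M (-1.05) fell. With the replicate block 351 genes changed, 113 up and 238 down, and the endothelial marker list (median -0.08) passed as well (adjusted p = 0.00238; adjusted p = 0.158 with an estimated correlation). The inflammatory list did not pass with array weights (adjusted p = 0.0696), and without non-transfected replicate 2 its mean went from -0.17 to -0.084 (adjusted p = 0.331) and that of the heat shock list from -0.089 to -0.056 (adjusted p = 0.0762). With median scaling TGFB2 and the inflammatory and cholesterol lists did not pass, and with the mean of probes CTSL and the inflammatory, p53 and heat shock lists did not. With 1 array left out in turn the inflammatory, heat shock, extracellular matrix, cholesterol and TGF-beta lists each lost the call in at least 2 cases, as did TGFB2.

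Against non-transfected HUVEC, NFAT5 siRNA changed 1445 genes, 682 up and 763 down (2971 with the replicate block; 570 up and 357 down with median scaling, which makes rises 61.5% of calls against 47.2%). HMOX1 (1.98) and CCN3 (2.05) rose and NPPB (-2.81) and CCL2 (-2.34) fell. KDR (0.98) and PECAM1 (0.61, adjusted p = 0.0440) rose against non-transfected cells as well.

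**Figure D3:**
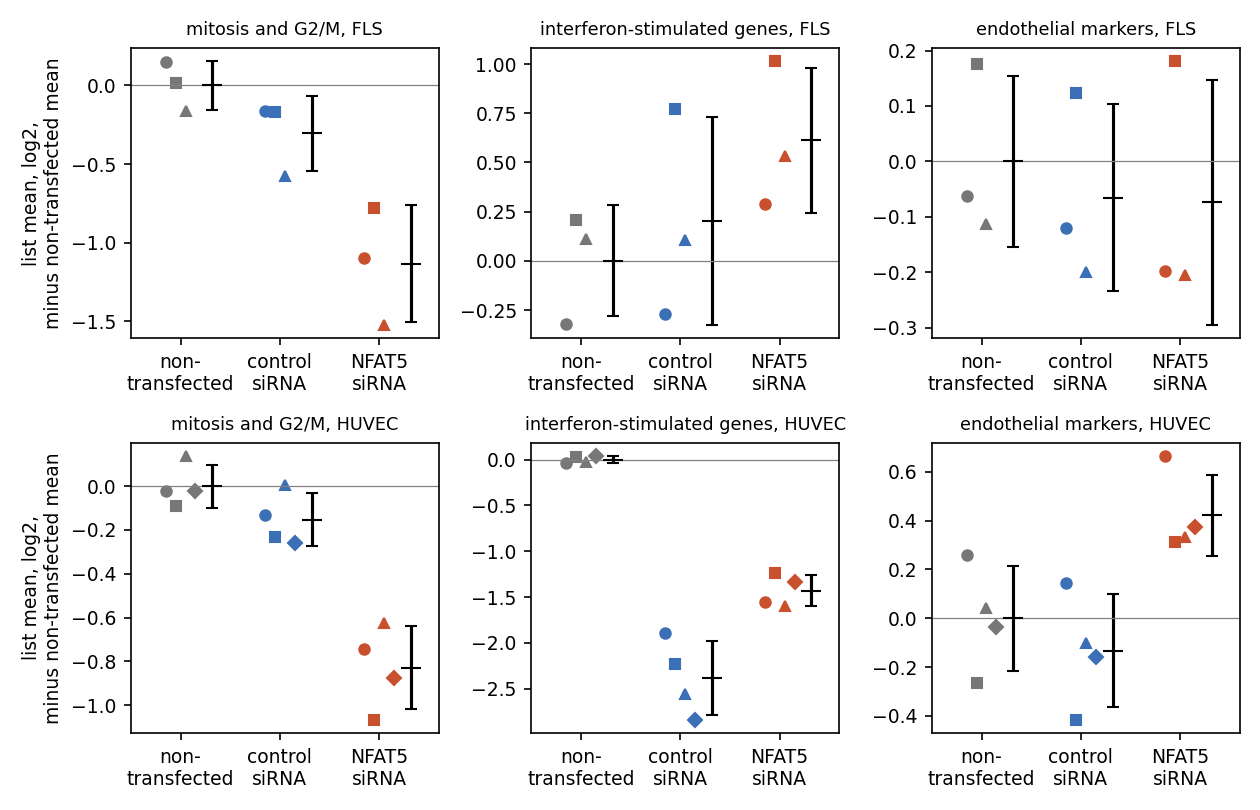
Mean log2 level of mitosis, interferon-stimulated and endothelial marker genes on each array, minus the mean of the non-transfected arrays of that cell type; symbol shapes are replicate numbers, bars the mean and SD, and each panel has its own scale. In HUVEC the interferon list lies between -1.60 and -1.24 with NFAT5 siRNA and between -2.84 and -1.90 with control siRNA.

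Whether the response differed between the kinds of cell was tested directly. GJB2 and GDF15 rose in FLS (3.27 and 2.79) and stood at -0.25 and 0.36 in HUVEC (GDF15 there adjusted p = 0.247; 0.01003 with the block), differences of -3.52 ± 0.51 and -2.42 ± 0.30 (HUVEC minus FLS, SE; adjusted p = 0.00206 and 0.000379). NPPB and TGFB2 fell in HUVEC (-3.32 and -1.97) and stood at -0.18 and 0.03 in FLS, differences of -3.14 and -1.999. The phosphatase DUSP3 rose in FLS (1.19) and stood at -0.12 in HUVEC, a difference of -1.31 that did not pass with median scaling (adjusted p = 0.0524). In the other direction ADAMTS9 (difference 2.55), CCN3 (2.66) and SAMD9 (1.36) rose in HUVEC, OSBPL7 differed by 1.59, and EHD4 by 1.31 after a change of -1.50 in FLS. In all 79 of 16957 genes differed, 42 higher and 37 lower in HUVEC, and 1095 with the replicate block. The count was 29 with median scaling, 30 with only the groups compared, and 26 without FLS NFAT5 siRNA replicate 3.

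Many calls were nonetheless shared. Among 16826 genes tested in both, 131 fell in both against 9.67 for independent lists (odds ratio 39.6, 95% interval 29.5 to 53.3, Fisher's exact p = 3.046e-122). Another 63 rose in both against 7.83 (odds ratio 13.2, 95% interval 9.39 to 18.3, Fisher's exact p = 1.623e-40). Both tests take genes as independent, while genes can move together (estimated correlation 0.66 for FLS mitosis genes), so these intervals are too narrow. No detection filter was applied. Genes too dim to be called in either kind of cell can lower the numbers for independent lists and raise both odds ratios. By how much was not tested. DR1, RECK, LEPROTL1, F3, NEK7, SPIN4 and RRM2 were among the shared falls, and NPC1, ZFYVE26 and CXCL1 among the shared rises. Across genes, which are not independent replicates, the log2 changes of the 2 kinds of cell correlated at Pearson r = 0.42 and Spearman rho = 0.35. With the replicate block 635 genes fell and 481 rose in both, with median scaling 63 and 31, with only the groups compared 70 and 27, and without FLS NFAT5 siRNA replicate 3 they were 25 and 9.

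**Figure D4:**
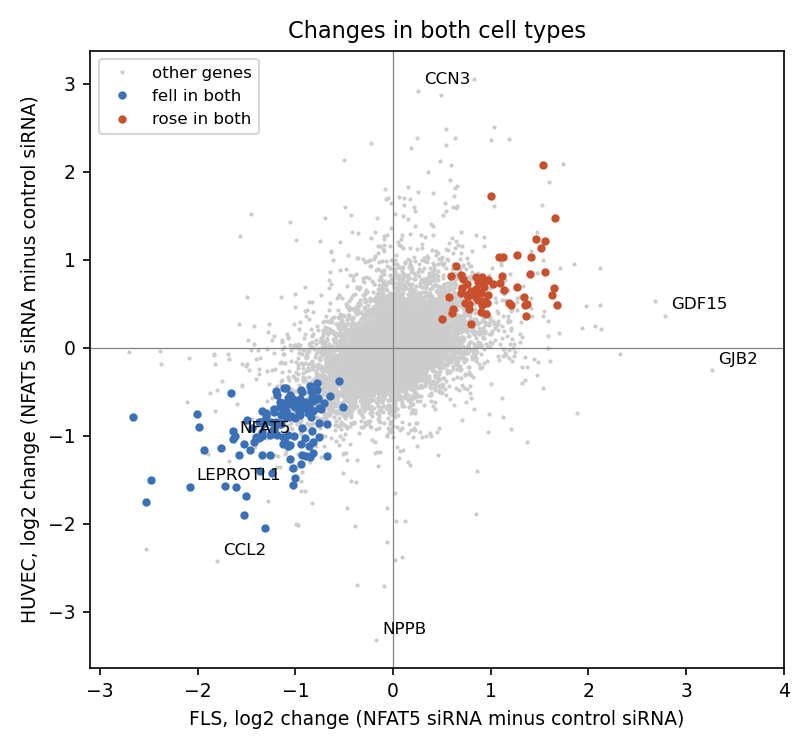
Log2 change of each gene with NFAT5 siRNA against control siRNA, FLS on the horizontal and HUVEC on the vertical axis; coloured points passed the test in the same direction in both. The 131 shared falls lie at the lower left and the 63 shared rises at the upper right, while GJB2 and NPPB moved in 1 kind of cell.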

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

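The tests of single explanations below were chosen after the pattern was seen, and for the number of unusual arrays, the direct siRNA effect, known targets of NFAT5, both normalization tests, the reagent, the mitosis pairs, the mitosis list against non-transfected cells and every count over regrouped arrays the deciding value had been seen as well. The list test of the difference between the kinds of cell was also chosen after the data were seen.

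Interferon-stimulated genes were far lower in both transfected HUVEC groups than in non-transfected HUVEC, and all 4 non-transfected arrays lay above every control siRNA array, which argues against 1 or 2 unusual arrays. An exchange of the non-transfected and control siRNA labels could also give this pattern and stays open: the 16 genes that fell with control siRNA in FLS (replicate block; median -0.87) had a median of 0.042 ± 0.0118 (SE over 4 pairs) in HUVEC, above 0 by more than its spread, with 4 of them below 0. This meets the prediction as first written, a median above 0. It lies below a bound on size taken from the FLS change, which assumes that both kinds of cell respond alike. That bound on size, and the spread over pairs, were set after the value was seen. The 14 genes that rose in HUVEC had a median of -0.0085 ± 0.0387 (SE over 3 pairs) in FLS, so neither set decides. With control siRNA the mitosis and replication lists fell and the p53 list rose in both kinds of cell. Under an exchange the HUVEC directions would be opposite to those in FLS. The list means moved the same way in 7 of 7 pairs of the same number, which restates these calls. Only the 4 HUVEC pairs bear on the HUVEC labels. Apart from p53 in FLS, these calls are lost with an estimated correlation (camera adjusted p = 0.311 or more). FLS and HUVEC need not respond alike, so these lists do not decide on an exchange either. An effect of the reagent and handling cannot be told apart from one of the siRNA, since no mock-transfected arm exists and both siRNA groups were low (median -1.41 for NFAT5 siRNA against non-transfected cells).

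Falls were shared between FLS and HUVEC more often than rises. With median scaling in place of quantile normalization, 63 genes fell in both against 2.52 for independent lists. The odds ratio was 53.6, with a lower 95% bound of 37.2. That bound takes genes as independent and is too high for genes that move together. For the 31 shared rises the odds ratio was 11.3. Dim genes, which were not filtered out, can raise both odds ratios. These values argue against quantile normalization as the cause of the sharing. The number of falls did depend on it: HUVEC falls among genes tested in both were 753 with quantile normalization and 275 with median scaling. A direct effect of this siRNA on other transcripts (odds ratio 39.6 for falls, 13.2 for rises) cannot be told apart from loss of NFAT5, because the sources used here do not give a second NFAT5 siRNA to compare with. That 0 known osmotic targets of NFAT5 were among the shared falls decides nothing, since none was called in FLS in the fit without the block. With the replicate block 3 rose and 2 fell in FLS. SLC38A2 was 1 of these falls (-0.89, limma adjusted p = 0.000493) and also fell in HUVEC. This 1 gene does not separate loss of NFAT5 from a direct effect either. In FLS 14 and in HUVEC 104 called genes fell further than NFAT5 itself, and 18 of the 131 shared falls belong to the replication or mitosis lists.

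Mitosis genes fell as a list with NFAT5 siRNA in both kinds of cell at the preset correlation, but not with an estimated one (adjusted p = 0.333 in FLS and 0.0834 in HUVEC). With the replicate block and an estimated correlation the list passed in HUVEC (camera adjusted p = 0.0283) and not in FLS (0.250). Both groups compared were transfected; that the list mean was lower with NFAT5 siRNA in 7 of 7 pairs of arrays restates the pattern and decides nothing on transfection as such. With median scaling the HUVEC mean change was still -0.53 ± 0.155 (SE, 4 pairs), which argues against quantile normalization. Loss of NFAT5 cannot be told apart from another effect of the siRNA here (median -0.88 against non-transfected HUVEC), since the sources used here give no second NFAT5 siRNA to compare with.

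Regrouping the arrays tested whether chance could give as many calls. For FLS the 10 splits of 6 arrays are too few for a share under 0.05: NFAT5 siRNA against control siRNA gave 387 genes and at most 0 in another split, and 6 lists, reached in 3 of 10 splits and at most 10. Control siRNA against non-transfected FLS gave 0 genes in all 10 splits and 4 lists, reached in 6 splits and at most 5. NFAT5 siRNA against non-transfected FLS gave 354 genes and at most 0 otherwise. In HUVEC the share over all 35 splits, which ignore the pairing, was under 0.05 for the gene counts, each reached by 1 split: 1573 genes (highest other 0), 123 genes (highest other 6) and 1445 genes (highest other 0). It was under 0.05 for the 11 lists with NFAT5 siRNA (1 of 35 splits, highest other 10), and chance was not excluded for the 9 lists with control siRNA (2 of 35, highest other 11). Among splits that part all pairs of a replicate number, 3 others in FLS and 7 in HUVEC, none reached the real list counts; their highest were 5 and 3 lists in FLS and 9 and 4 in HUVEC. These splits, which keep to the pairing, are too few in either kind of cell for a share under 0.05, so they do not set these counts beyond chance. The highest list counts came from splits that part 1 of 3 pairs in FLS and 2 of 4 in HUVEC.

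Over 100 drawn splits within each kind of cell, the 79 genes that differed between FLS and HUVEC were reached by 2 (highest other 505), a share under 0.05. Each regrouped split takes away the NFAT5 siRNA effect in at least 1 kind of cell, and most splits do so in both. This share therefore does not test whether the 2 effects were equal. The split with 505 genes, several times the real count, kept the real FLS groups, with 387 genes there, and regrouped HUVEC with 0. Other regrouped splits that kept the real FLS groups gave between 42 and 73 genes, and why this split gave more was not tested. The split with 505 genes is 1 of the 6 other drawn splits that part all pairs, too few for a share under 0.05. The number of 79 is therefore not set beyond chance by splits that keep to the pairing. The 63 shared rises and 131 shared falls were reached by 1 split each (highest other 0), which decides nothing, since no regrouped split called genes in both kinds of cell. The 8 lists that differed were reached by 19 of 100 splits (highest other 10), so chance was not excluded for that number.

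The change with NFAT5 siRNA differed between the kinds of cell for 79 genes. The differences (HUVEC minus FLS, log2) were 1.59 for OSBPL7, 2.55 for ADAMTS9, 1.31 for EHD4, 2.66 for CCN3, 1.36 for SAMD9, -3.14 for NPPB, -1.31 for DUSP3, -2.42 for GDF15, -1.999 for TGFB2 and -3.52 for GJB2. By lists, the median difference was 0.29 for angiogenic factors, 0.33 for adhesion molecules, 0.12 for replication, 0.17 for mitosis, 0.38 for interferon-stimulated genes, 0.17 for hypoxia genes, 0.58 for endothelial markers and 0.23 for smooth muscle markers. None of these 8 lists passed with an estimated correlation (lowest adjusted p = 0.0703). Endothelial marker means in FLS (6.73 to 7.12) lay near the median signal of 7.11, where levels are poorly measured. For interferon-stimulated genes, SAMD9 among them, HUVEC control siRNA lay far below non-transfected cells (median -2.20). Against non-transfected cells their median with NFAT5 siRNA was 0.57 in FLS and -1.41 in HUVEC.

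Single HUVEC arrays stood apart from the other 3 of their group in 15 of 290 groups tested, where chance gives about 1 in 20. With NFAT5 siRNA these were IFI6 at a log2 level of 12.3 (others 11.7 to 11.8), SLC7A5 at 11.01 (10.5 to 10.5) and JAG1 at 10.8 (10.3 to 10.3), all on replicate 2, and CCN1 at 13.9 (14.0 to 14.0). With control siRNA they were NFAT5 at 9.69 (9.09 to 9.15), CXCL2 at 5.84 (6.74 to 6.88), TNFRSF10B at 12.9 (12.6 to 12.6), FASN at 13.8 (13.9 to 14.0) and ESAM at 11.2 (12.1 to 12.1). Without transfection they were IFI6 at 13.6 (13.8 to 13.9) and PARP9 at 12.4 (12.3 to 12.3). List means stood apart for extracellular matrix (9.83) and angiogenic factors (9.05) with control siRNA, cholesterol genes (10.5) without transfection and endothelial markers (10.9) with NFAT5 siRNA.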

How the results depend on the processing

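A filter on dim probes and the replicate block with an estimated correlation were chosen after seeing the data. Of 232 named genes and lists, 228 kept direction and side of the threshold without background correction, 207 with median scaling, 228 with deposited values, 211 with the mean of probes, 221 with only the groups compared, 212 with the block and 223 with array weights; the cause of the changes was not tested. Among these 232 results, which hold no list without a call except the osmotic targets, the block ended 0 calls and added 20, all genes. Outside them the block added the inflammatory and fibroblast lists for NFAT5 siRNA in FLS and the endothelial marker list for control siRNA in HUVEC. Over all genes, 1571 of the 1573 HUVEC calls against control siRNA and 1443 of 1445 against non-transfected cells were called in both fits. A filter on detection on every array could not be run without detection p-values, no filter is the setting used, and no slide is given. No background estimate per array limits what can be said of dim probes.

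Counts that moved by over 1.5 times follow. For FLS, NFAT5 siRNA against control siRNA (387), they were 245 with median scaling, 156 with only the groups compared (fewer arrays to estimate the spread), 2537 with the replicate block and 614 with probes above the median signal. Against non-transfected FLS (354) they were 129 with only the groups compared, 2526 with the block, 553 with array weights and 587 with bright probes. Control siRNA in FLS gave 16 with the block. In HUVEC the block gave 3115, 351 and 2971, and median scaling 927 against non-transfected cells. The difference between the kinds of cell (79) was 124 without background correction, 29 with median scaling, 128 with deposited values, 30 with only the groups compared, 1095 with the block, 134 with array weights and 370 with each kind of cell's own spread. Shared rises (63) and falls (131) were 31 and 63 with median scaling, 27 and 70 with only the groups compared, 481 and 635 with the block, and 174 and 294 at an unadjusted p under 0.01; bright probes gave 105 shared rises. With an estimated correlation 0 lists in FLS and 0 in HUVEC passed for NFAT5 siRNA, and 1 in each for control siRNA; with the block added these were 0, 6, 0 and 1.

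Each array was left out in turn. Having 1 array fewer can lower a count by itself, but counts also differed with the array left out, and some rose. FLS NFAT5 siRNA against control siRNA ranged from 53 to 300: without control siRNA replicates 1, 2 and 3 it was 89, 69 and 171, without NFAT5 siRNA replicates 1, 2 and 3 it was 113, 224 and 53, and without non-transfected replicate 2 it was 230. Against non-transfected FLS it ranged from 57 to 306, with 61, 57 and 204 without non-transfected replicates 1, 2 and 3, 90, 231 and 65 without NFAT5 siRNA replicates 1, 2 and 3, and 204 without control siRNA replicate 2. Control siRNA in FLS stayed at 0. HUVEC counts ranged from 1144 to 1583, from 112 to 126 and from 1045 to 1454. The difference between the kinds of cell ranged from 26 to 88, with 49, 33 and 51 without FLS control siRNA replicates 1, 2 and 3, 26 without FLS NFAT5 siRNA replicate 3, 47 and 50 without HUVEC control siRNA replicates 2 and 4, and 49 and 43 without HUVEC NFAT5 siRNA replicates 3 and 4. Shared rises ranged from 9 to 65 and shared falls from 25 to 134, lowest without FLS NFAT5 siRNA replicate 3; without FLS control siRNA replicates 1, 2 and 3 they were 18, 12 and 28 rises and 43, 37 and 84 falls, without NFAT5 siRNA replicate 1 they were 16 and 53, and without replicate 2 rises were 33. Lists in FLS ranged from 2 (without control siRNA replicate 1) to 8 and from 4 to 6, and in HUVEC from 10 to 11 and from 6 to 9.

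The mean log2 change of osmotic NFAT5 targets in FLS, near 0 and not called, turned negative for NFAT5 siRNA without background correction (-0.0062), with median scaling (-0.028), deposited values (-0.0025), array weights (-0.016) and bright probes (-0.0046), and for control siRNA with median scaling (-0.0032). With 1 array left out it ranged from -0.053 to 0.043 and from -0.050 to 0.066; interferon genes in FLS with control siRNA ranged from -0.074 to 0.44, negative without control siRNA replicate 2.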

Other observations

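Among the genes called in both kinds of cell, 34 fell and 9 rose at least 2-fold in both, and 4 were called in opposite directions. Shared falls outside the genes named so far included PLSCR4 (log2 change -1.53 in FLS and -1.90 in HUVEC), TMEM14B (-1.73 and -1.58), the methionine salvage enzyme APIP (-1.51 and -1.69) and the vesicle coat GTPase SAR1A (-1.61 and -1.59). Shared rises included the lysosomal signalling GTPase RRAGD (1.51 and 1.13), the pseudokinase TRIB1 (1.46 and 1.23) and the ubiquitin ligase UBR4 (1.00 and 1.72). These genes were picked after their values were seen, as large changes past limma's threshold in both.

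With control siRNA, 1 of the 16 genes that fell in FLS under the replicate block also fell in HUVEC, the opioid growth factor receptor OGFR (-1.05 and -0.69), chosen after its values were seen. In HUVEC HLA-B (-2.56) and PSME2 (-1.12) fell against non-transfected cells, also chosen after their values were seen.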
